A study of Homo sapiens with 12 samples.

How the data were processed

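RNA from 12 samples was measured on Illumina bead arrays, with 3 arrays in each of 4 groups. The groups were SKOV3ip1 cells alone, SKOV3ip1 cells after co-culture with adipocytes, adipocytes alone, and adipocytes after co-culture with SKOV3ip1 cells. Per the labels, the co-culture held 1 volume of packed cancer cells to 3 volumes of packed adipocytes, in DMEM:F12 with 0.1% bovine serum albumin. The labels number the samples but do not say whether these came from separate cultures or donors. The spread behind every p-value is therefore the spread between these samples, which may be technical.

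The deposited non-normalized table gave an intensity and a detection p-value for each of 47309 probes on every array, on a linear scale. The authors' processed table held an intensity that was background-subtracted and quantile-normalized, also on a linear scale, with the same median of 4 on every array. The submitters' processing notes name GenomeStudio 2011.1 and Partek 6.6 without giving the role of each. Every column of the processed table correlated best, by rank, with the raw array of the same sample.

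Raw intensities were corrected for background and quantile-normalized over all 12 arrays with neqc in limma 3.58.1 on R 4.3.3, using the detection p-values, an offset of 16 and log2 values. Probe names came from an annotation table of 30115 probes from 2016, of which 30107 carried 1 gene symbol and 8 carried several. The other 17194 probes carried no gene there and were kept apart. Of the annotated probes, 30068 had an identifier that matched the gene table and 47 identifiers did not match. Probes on the Y chromosome and for X-inactivation RNAs, 144 in all, were left out. The 19947 genes that remained were each read from the probe with the highest mean over the 12 arrays, and 6657 of them had more than 1 probe. A gene was tested if it was detected, with a detection p-value under 0.01, on all arrays of at least 1 of the groups compared.

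Each response was co-cultured minus alone within 1 cell type, and the baseline difference was adipocytes alone minus SKOV3ip1 alone. Each used lmFit and eBayes in limma on the 6 arrays concerned, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference between the responses was the interaction in a limma model over all 4 groups, with array weights shared within a cell type (0.632 for SKOV3ip1 and 1.58 for adipocytes). Changes are log2 values with the standard error of the limma model, and n is 3 arrays per group throughout. A gene not detected on any array of 1 group has only a lower bound for its fold. That bound sets the undetected group at the lowest detected signal of each array, or at its own signal where higher, and a list median is given a second time with such genes at their bound where this changes it. For array data the number of arrays limits the precision, and with 3 against 3 a permutation test cannot give a p-value below 0.1.

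A change was counted as against mixing when the co-cultured mean lay above, or below, the means of both groups of the other cell type, since added RNA of that other cell type cannot produce it. The apparent share of other-cell RNA was computed from genes at least 16-fold higher in the other cell type alone and undetected on every array of the own cell type alone. For each such gene it was the rise in co-culture divided by the gap between the cell types alone, on the linear scale, with the median over genes taken per array.

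Gene groups were 30 lists, 8 of cell type markers and 22 of programmes, with 545 members of which 38 had no probe named here. The cell type lists were adipocyte identity, epithelial cancer cell, fibroblast and preadipocyte, mesothelial, endothelial, macrophage, T cell and red blood cell. The programmes were fatty acid uptake and lipid droplet, fatty acid oxidation, PPAR target, fatty acid synthesis, cholesterol synthesis, glycerol-3-phosphate and triglyceride synthesis, lipolysis, hypoxia (HIF) target, glycolysis, oxidative phosphorylation, NF-kB and inflammatory cytokine, interferon response, immediate early, ATF4 and amino acid response, unfolded protein response, cytosolic heat shock, NRF2 target, metallothionein, cell cycle, extracellular matrix and protease, epithelial to mesenchymal transition, and ribosomal protein. Lists with at least 4 tested genes were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Another 4 lists (acute phase, glucocorticoid target, TGF-beta target, retinoic acid target) were written after the leading genes had been seen, without those genes.

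Genes were named by a rule. For each response these were the 6 that rose most and the 6 that fell most, among called genes whose groups of 3 arrays did not overlap, and the same again among changes against mixing. Up to 4 members of each list with the smallest adjusted p were added, and the 5 largest per sign for the baseline difference and for the difference between responses. From the list members, the text quotes mainly those in SKOV3ip1 that kept their call when the number of detected probes per array was a covariate, a choice made after the values were seen. The groups, comparisons, tests, the 30 lists, this rule and most alternatives were fixed before the data were examined.

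Alternatives planned in this way were other background correction and scaling, the authors' processed values, other detection filters, all probes, a replicate block, no array weights, a shared spread over the 4 groups, an intensity trend, a minimum change, other gene choices for the apparent share, and leaving out each array. Alternatives added later were the number of detected probes as a covariate, the removal of both SKOV3ip1 replicate 1 arrays, the subtraction of the apparent share of other-cell RNA, and the list tests under other scaling. The authors' processed values, with the same offset of 16 added before the log2, differ little from neqc by construction. Their changes correlated across genes with the ones reported at 1.000 in SKOV3ip1 and 0.999 in adipocytes, so they are no independent check.

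The replicate numbers in the labels were checked for pairing by correlating, across genes, the deviations from the group mean of same-numbered samples. In SKOV3ip1 these correlations ran from 0.287 to 0.614, and 3 of 6 samples matched their own number best. In adipocytes they ran from -0.03 to 0.14, with 3 of 6 matched best, and between the cell types alone from -0.03 to 0.07, with 2 of 6. In SKOV3ip1 only replicate 1 stood apart, at 0.614 with its own number. SKOV3ip1 alone replicate 1 was at -0.609 and -0.435 with co-cultured replicates 2 and 3. Replicates 2 and 3 showed no clear match by number. The deviations within a group of 3 cancel out, so the values for replicates 2 and 3 partly mirror that of replicate 1 and are weak evidence on pairing. Alone replicate 3 was at 0.466 with co-cultured replicate 2 and at 0.287 with co-cultured replicate 3. The numbers thus gave no clear pairs beyond replicate 1, and the replicate block was kept as an alternative. No block for array slides was fitted.

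The steps were tested on simulated data with the residual spread of each comparison and 200 changed genes. At a change of 1 on the log2 scale, 58% were recovered among 9743 genes for the SKOV3ip1 response, 98% among 9979 for adipocytes and 61% among 11270 for the difference. At 0.5 the shares were 2%, 46% and 8%. False calls made up 3.23%, 3.36% and 9.21% of the calls. These rates hold for noise independent between genes and few changed genes, unlike the SKOV3ip1 data, where 55.4% of tested genes were called. A simulated admixture of 3%, with 1 ratio for every gene, was recovered as 2.99% and 3.01%. That recovery checks the arithmetic only, since the mixture was built by the formula that the share inverts. Plots were drawn with matplotlib 3.10.9, and small tables made with pandas 2.3.3. Genes on the Y chromosome were not analysed here, nor was any splicing or sequence variant.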

Results

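SKOV3ip1 is a human ovarian cancer cell line, and the adipocytes were primary cells from the human omentum, a fatty tissue of the abdomen. Both were profiled alone and after co-culture, which addresses how each cell type changes in the presence of the other. Each of the 12 arrays measured total RNA of a sample labelled as 1 cell type, though co-cultured adipocyte arrays carried an apparent SKOV3ip1 share of 1.40%. SKOV3ip1 alone gave 15113 ± 508 detected probes (SD, n = 3) and co-cultured SKOV3ip1 gave 16656 ± 1007. Adipocytes alone gave 16746 ± 371 and co-cultured adipocytes 16512 ± 355. Median raw intensity per array lay between 87.4 and 97.2, and 11026 probes were detected on all 12 arrays. Correlations between arrays of 1 group ran from 0.977 to 0.996. The first principal component held 88.5% of the variance and the second 7.52%.

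The baseline comparison asked how the cell types differed before contact. All 22 tested adipocyte identity genes were higher in adipocytes (median log2 difference 5.23, limma camera adjusted p = 3.6e-09, 0.0551 with an estimated correlation), and all 17 tested epithelial cancer cell genes were lower (median -5.03, adjusted p = 6.6e-07, 0.0863 with an estimated correlation). By fitted values, genes higher in adipocytes were led by ADH1A, an alcohol dehydrogenase, at least 427-fold, and GPX3, a secreted glutathione peroxidase, at least 409-fold. PLIN2, a lipid droplet coat protein, was at least 364-fold higher, CCL2, a monocyte chemokine, at least 329-fold and MAOA, a monoamine oxidase, at least 282-fold. All were undetected in SKOV3ip1 alone, so these folds are lower bounds and do not fix the order. SKOV3ip1 cells were led by KRT19, an epithelial keratin (-9.10 ± 0.13, detected on 1 of 3 adipocyte arrays). MAL, EEF1A2, CD70 and CD24 were at least 366-fold, 212-fold, 180-fold and 176-fold higher there.

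Of 10973 genes tested at baseline, 9703 were called, 4739 higher in adipocytes and 4964 higher in SKOV3ip1. The groups of 3 arrays were separate for 89.2% of genes, against 10% by chance. Cell cycle genes were lower in adipocytes for 27 of 28 members (median -3.86, adjusted p = 1.9e-07, 0.123 with an estimated correlation), as were 16 of 17 glycolysis genes (median -1.80, adjusted p = 0.0019, then 0.0971). NF-kB and inflammatory cytokine genes were higher for 22 of 25 (median 3.51, adjusted p = 1.9e-06, then 0.0971), and interferon response genes for 15 of 21 (median 1.44, adjusted p = 0.0042, then 0.104). Of 26 lists tested, 15 passed with camera, 12 higher and 3 lower in adipocytes. With an estimated correlation 0 passed, although 9 had an unadjusted p under 0.05, and with fry 24 did.

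The response of SKOV3ip1 was led by CXCL8, the chemokine interleukin-8, which rose 19.5-fold (log2 4.28 ± 0.28, adjusted p = 4.3e-05, n = 3 per group, detected on 2 of 3 arrays alone). CXCL1, a related chemokine, rose 4.96-fold (2.31 ± 0.15). TCIM, a regulator of Wnt signalling, rose by 2.15 ± 0.28, PRDX3, a mitochondrial peroxidase, by 2.04 ± 0.27 and CLDN1, a tight junction protein, by 2.03 ± 0.19. PDK4, a kinase that limits glucose oxidation, was undetected alone and at least 2.78-fold higher in co-culture. FOXS1, a forkhead factor, fell most (-2.89 ± 0.18), followed by LYPD1 (-2.45 ± 0.16) and DHRS3, a retinaldehyde reductase (-2.35 ± 0.16). BIRC7, an apoptosis inhibitor, CGB1, a chorionic gonadotropin subunit, and PROC, protein C, fell by 2.09, 2.06 and 2.05.

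Among changes against mixing, which adipocyte RNA cannot produce, TCIM and CLDN1 again led the rises, with CDK1, the mitotic kinase (1.83 ± 0.23), PTPRR (1.78 ± 0.27), MORF4L2 (1.74 ± 0.24) and MAL2 (1.74 ± 0.27). The falls were led by DHRS3, FAM178B (-1.91 ± 0.19), PMEPA1, an inhibitor of TGF-beta signalling (-1.67 ± 0.15), KLHDC8B (-1.62 ± 0.16), CLIP3 (-1.57 ± 0.16) and RARRES2, the adipokine chemerin (-1.47 ± 0.17). All 21 leading genes kept their call and sign with the number of detected probes as a covariate. In that fit CXCL8 rose by 3.64 and FOXS1 fell by 2.52, while other rises shrank by over 1.5 times, PTPRR to 0.89, MAL2 to 0.89, PRDX3 to 1.21, MORF4L2 to 1.04 and TCIM to 1.33.

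**Figure D1:**
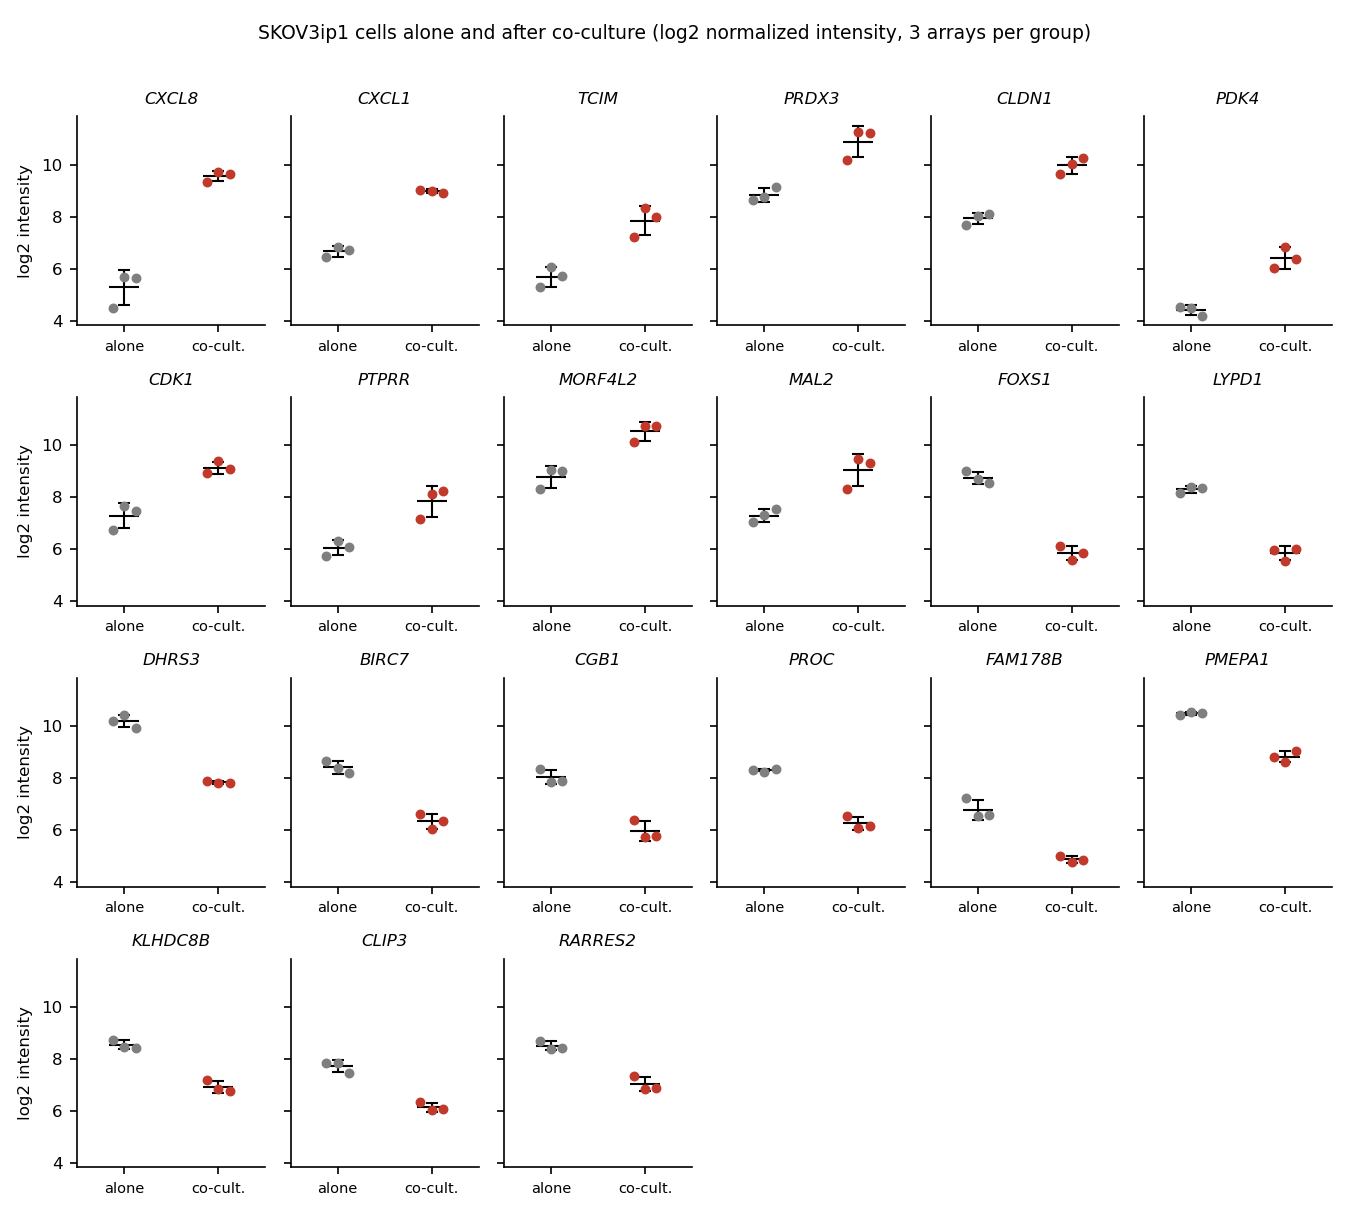
Normalized log2 intensity of leading genes in SKOV3ip1 cells alone (grey) and co-cultured (red); points are arrays and bars the mean ± SD of 3 arrays. CXCL8 rose by 4.28 and FOXS1 fell by 2.89.

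Of 9743 genes tested in SKOV3ip1, 5393 (55.4%) were called, 2616 up and 2777 down, of which 569 and 239 changed at least 2-fold. The groups were separate for 63.5% of genes, against 10% by chance. Changes against mixing made up 907 of the rises and 640 of the falls. The split depended on scaling. With median scaling 2122 rose and 3575 fell, and the median change over all genes was -0.20 in place of -0.06, so each change is relative to the scaling chosen. Detected probes differed with condition, and with their number as a covariate 837 genes passed, 799 of them shared. In that fit the median absolute change of the 5393 called genes was 0.35 in place of 0.68, with a median standard error of 0.166 in place of 0.171, so calls ended through smaller changes, and the covariate cannot be parted from condition. Replicate 1 stood apart in both SKOV3ip1 groups, and without both of its arrays 7520 passed, 5345 of them shared. The count changed by more than 1.5 times without SKOV3ip1 alone replicate 1 (3420), co-cultured replicate 2 (3160) or co-cultured replicate 3 (3115).

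Cell cycle genes were the 1 list of 26 to pass in SKOV3ip1: 16 rose, 2 fell and 15 did not pass, with 15 of the rises against mixing. Their median was 0.38, or 0.37 with 1 gene at its bound (camera adjusted p = 0.026, 0.763 with an estimated correlation, range 0.0153 to 0.763 over the alternatives). CCNA2, an S phase and mitotic cyclin, rose by 1.25 ± 0.16, RRM1 and RRM2, the ribonucleotide reductase subunits, by 1.59 ± 0.25 and 1.53 ± 0.22. The list also did not pass with median scaling (adjusted p = 0.0891), without co-cultured replicate 1 (0.116) or without both replicate 1 arrays (0.0995). With an estimated correlation in camera 0 of the 26 lists passed, 0 at an unadjusted p under 0.05, and with fry 11 did.

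The inflammatory and stress lists did not pass in SKOV3ip1. Of 16 NF-kB and inflammatory cytokine genes 9 rose and 3 fell (median 0.47, or 0.25 with 3 genes at their bound, adjusted p = 0.0824). NFKBIZ, an NF-kB cofactor, rose by 1.66 ± 0.19 and SOD2, the mitochondrial superoxide dismutase, by 1.16 ± 0.14. Of 14 unfolded protein response genes 6 rose and 0 fell (median 0.26, adjusted p = 0.0760), among them DNAJB11 (1.02 ± 0.17). Of 11 genes on the cytosolic heat shock list 6 rose and 1 fell (median 0.90, camera adjusted p = 0.0824). HSP90AA1 was at 1.20 ± 0.21, HSPH1 at 1.11 ± 0.19 and HSPA8 at 0.93 ± 0.15. HSPD1 (1.02) and HSPE1, mitochondrial chaperonins also on that list, were among the rises, and the median was the value of HSPE1. HSPB1 fell (-0.48), while HSPA1B (0.22), HSPA1A (0.09), DNAJB1 (-0.07) and BAG3 (-0.05) did not pass. Of 11 NRF2 target genes 6 rose and 2 fell (median 0.67, adjusted p = 0.251), where TXNRD1, thioredoxin reductase, rose by 1.40 ± 0.25 and HMOX1, heme oxygenase, fell by 1.03. Interferon response genes rose for 7 and fell for 1 of 15 (median 0.16, adjusted p = 0.339), with IFI27 up by 0.63 ± 0.14 and OAS2 at least 1.35-fold. ATF4 and amino acid response genes rose for 6 and fell for 2 of 19 (adjusted p = 0.554), with MTHFD2 up by 1.13 and PHGDH at -0.99. Immediate early genes rose for 3 and fell for 3 of 16 (adjusted p = 0.804), and DUSP1, a phosphatase, rose by 1.39 ± 0.16. Metallothionein genes rose for 0 and fell for 2 of 5 (adjusted p = 0.804).

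Lipid genes in SKOV3ip1 moved in both directions, as did all 9743 genes tested, of which 2616 rose and 2777 fell. Of 11 fatty acid uptake and lipid droplet genes 6 rose and 2 fell (median 0.53, or 0.50 with 1 gene at its bound, adjusted p = 0.385). CAV1, caveolin, rose by 1.49 ± 0.20, FABP5, a fatty acid carrier, by 0.82 ± 0.15 and G0S2, a lipolysis inhibitor, at least 1.41-fold. Fatty acid synthesis genes rose for 0 and fell for 4 of 12 (adjusted over the list alone, 3 fell, median -0.08, adjusted p = 0.761), led by SREBF1, a lipogenic transcription factor (-1.30 ± 0.19). Cholesterol synthesis genes rose for 4 and fell for 6 of 15 (adjusted over the list alone, 5 rose and 6 fell, adjusted p = 0.832), with MVK at -1.15 ± 0.18. Fatty acid oxidation genes rose for 5 and fell for 3 of 15 (adjusted p = 0.908), including ETFA at 1.42 ± 0.20. PPAR target genes rose for 3 and fell for 1 of 10 (adjusted p = 0.804), with UCP2 at -1.07 ± 0.16. Glycerol-3-phosphate and triglyceride synthesis genes rose for 3 and fell for 2 of 8 (adjusted p = 0.776), with GPAT3 at 1.18 ± 0.17. Lipolysis genes rose for 2 and fell for 2 of 5 (camera adjusted p = 0.854), with ADORA1, an adenosine receptor, at -1.42 ± 0.16. That list also holds the inhibitor G0S2, so its counts give no direction for lipolysis.

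Hypoxia (HIF) target genes rose for 9 and fell for 4 of 23 in SKOV3ip1 (adjusted over the list alone, 10 rose, median 0.28, adjusted p = 0.200), with BNIP3, a mitophagy receptor, at 1.37 ± 0.15, NDRG1 at 0.92 ± 0.14 and LOX at least 1.28-fold. Glycolysis genes rose for 1 and fell for 5 of 17 (adjusted over the list alone, 3 fell, median -0.27, adjusted p = 0.554). Oxidative phosphorylation genes rose for 11 and fell for 2 of 27 (median 0.08, -0.23 with median scaling, adjusted p = 0.200), with SDHD at 1.43 ± 0.22. Extracellular matrix and protease genes rose for 3 and fell for 5 of 18 (adjusted p = 0.761). MMP1, interstitial collagenase, rose by 1.65 ± 0.20, while COL1A1 fell by 1.31 and TGFBI by 1.32. Epithelial to mesenchymal transition genes rose for 1 and fell for 2 of 10 (adjusted p = 0.804), and ribosomal protein genes rose for 5 and fell for 1 of 26 (adjusted over the list alone, 2 and 0, adjusted p = 0.554).

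Of the cell type markers in SKOV3ip1, epithelial cancer cell genes rose for 1 and fell for 6 of 17 (median -0.29, adjusted p = 0.142), with KRT7 at -1.75 ± 0.24 and ELF3 at -1.29 ± 0.17. Mesothelial genes rose for 0 and fell for 3 of 4 (median -0.52, adjusted p = 0.200). Fibroblast and preadipocyte genes rose for 3 and fell for 3 of 6 (adjusted p = 0.908), with MFAP5 up by 0.99 ± 0.16 and DCN, decorin, at least 1.38-fold. Adipocyte identity genes rose for 2 and fell for 2 of 6 (adjusted over the list alone, 3 fell, adjusted p = 0.804). The macrophage genes CD68 (-0.07) and AIF1 (-0.12) did not pass, nor did the endothelial gene RAMP2 (-0.14), while PECAM1 rose by 1.00 ± 0.18, though not with the covariate. The red blood cell gene HBA2 rose by 0.46 with an adjusted p = 0.044, a call lost with median scaling, and 0 T cell genes were detected. The median, the mean and the camera direction differed in sign for PPAR target, fatty acid oxidation, cholesterol synthesis, lipolysis, metallothionein, fibroblast and preadipocyte, and epithelial to mesenchymal transition genes. With median scaling the medians of cholesterol synthesis, oxidative phosphorylation, immediate early, ATF4, metallothionein, epithelial to mesenchymal transition and ribosomal protein genes changed sign.

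The response of adipocytes was led by ORM1, an acute phase plasma protein, which rose 34.1-fold (log2 5.09 ± 0.11, adjusted p = 6.8e-10, n = 3 per group). ORM2, its close relative, rose by 4.68 ± 0.11. Genes of the epithelial cancer cell list also rose: KRT19 by 4.33 ± 0.14 (detected on 1 of 3 arrays alone), CD24 at least 16.4-fold and EPCAM, an epithelial adhesion protein, at least 12.9-fold, with MAL at least 13.1-fold. Interferon-induced genes fell most, with IFI44L at -3.40 ± 0.19, MX2 at -3.18 ± 0.19, OAS2 at -2.87 ± 0.15, IFI44 at -2.71 ± 0.12, IFI27 at -2.63 ± 0.19 and IFIT3 at -2.53 ± 0.13.

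Among changes against mixing, which SKOV3ip1 RNA cannot produce, ORM1 and ORM2 again led the rises. They were followed by SAA2, a serum amyloid (3.65 ± 0.13), CHI3L2, a chitinase-like protein (2.96 ± 0.15), HP, haptoglobin (2.53 ± 0.12), and SAA4 (2.19 ± 0.12). The falls there were again led by IFI27, followed by ISG15, a ubiquitin-like interferon product (-2.19 ± 0.23), HERC6 (-1.96 ± 0.12), OAS3 (-1.66 ± 0.15), IRF7, an interferon regulatory factor (-1.51 ± 0.11), and IFITM1 (-1.49 ± 0.17). All 21 leading genes kept their call and sign with detected probes as a covariate and with the apparent SKOV3ip1 share subtracted.

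**Figure D2:**
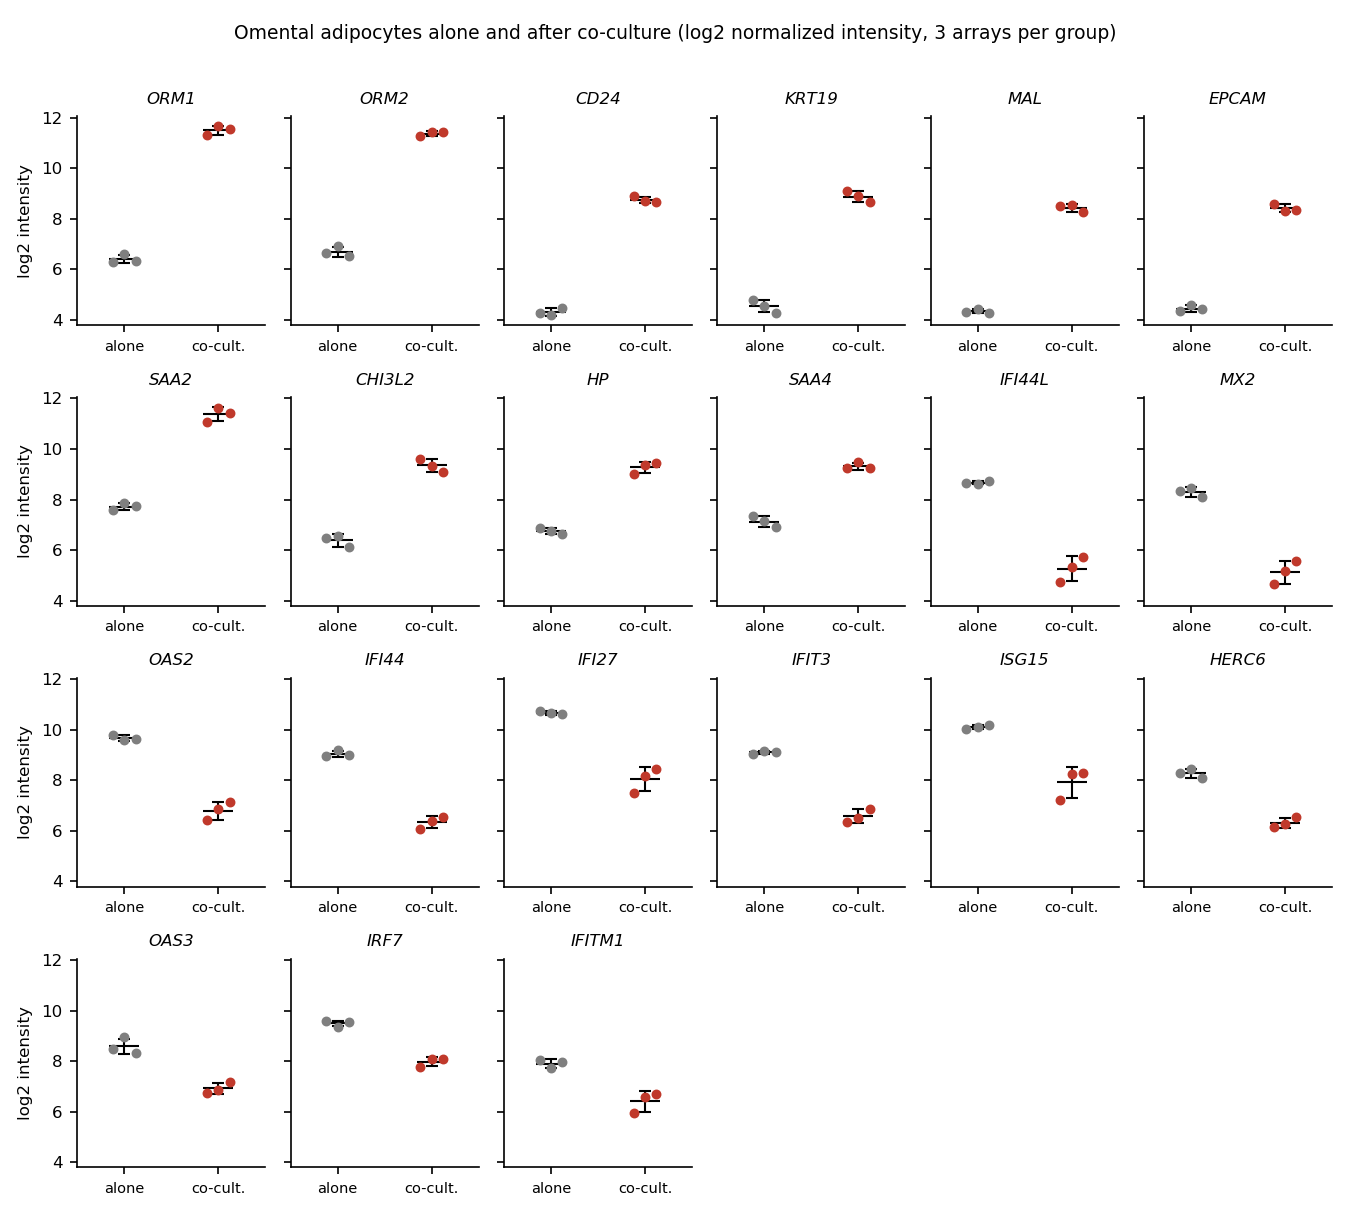
Normalized log2 intensity of leading genes in adipocytes alone (grey) and co-cultured (red); points are arrays and bars the mean ± SD of 3 arrays. ORM1 rose by 5.09 and IFI44L fell by 3.40.

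Of 9979 genes tested in adipocytes, 2097 (21.0%) were called, 1051 up and 1046 down, of which 151 and 56 changed at least 2-fold. The groups were separate for 38.0% of genes, against 10% by chance. Changes against mixing made up 302 of the rises and 233 of the falls. With detected probes as a covariate 1735 passed, 1636 of them shared. With the apparent share subtracted 1806 passed, 1787 of them shared. With its 90th percentile subtracted 1585 passed, 1379 of them shared and 62 with the opposite sign.

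All 21 interferon response genes tested in adipocytes fell, 9 of them against mixing (median -1.75, camera adjusted p = 2.0e-24, 0.115 with an estimated correlation, range 2.8e-28 to 0.115 over the alternatives). The list mean on arrays of adipocytes alone was 8.91, 8.88 and 8.91, and on co-cultured arrays 6.76, 7.16 and 7.28. ATF4 and amino acid response genes rose for 1 and fell for 9 of 18 (adjusted over the list alone, 10 fell, median -0.35, adjusted p = 0.00036, then 0.0795), among them PSAT1, a serine synthesis enzyme (-1.42 ± 0.11), STC2 (-1.06 ± 0.09) and ASNS, asparagine synthetase (-1.04 ± 0.10). NRF2 target genes rose for 0 and fell for 4 of 10 (adjusted over the list alone, 6 fell, median -0.32, adjusted p = 0.0033, then 0.115), with SRXN1 at -0.66 and GCLM at -0.65. Immediate early genes rose for 0 and fell for 7 of 18 (adjusted over the list alone, 9 fell, median -0.25, adjusted p = 0.0036, then 0.294), with KLF6 and ATF3 both at -0.42. The values with an estimated correlation, where none of these passed, were the highest over the alternatives, and the lowest were 1.5e-05, 0.00070 and 0.00093 for the last 3.

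Cholesterol synthesis genes rose in adipocytes for 13 and fell for 0 of 16 (adjusted over the list alone, 13 rose and 1 fell, median 1.03, adjusted p = 7.2e-12, 0.0504 with an estimated correlation), 4 of them against mixing. MSMO1, a sterol oxidase, rose by 1.45 ± 0.09, DHCR7, the last enzyme of the pathway, by 1.31 ± 0.09, ACAT2 by 1.23 ± 0.09 and INSIG1, a sterol sensor, by 1.16 ± 0.09. Fatty acid synthesis genes rose for 5 and fell for 0 of 12, with 1 rise against mixing (adjusted over the list alone, 6 rose and 1 fell, median 0.20, adjusted p = 0.0021, then 0.181). ELOVL6, a fatty acid elongase, was at 1.30 ± 0.10, ACLY, ATP citrate lyase, at 0.76 ± 0.10 and SREBF1 at 0.76 ± 0.13. Metallothionein genes rose for 5 and fell for 0 of 7, all 5 against mixing (adjusted over the list alone, 6 rose, median 0.60, adjusted p = 0.00038, then 0.347), with MT1G at 0.80 ± 0.14 and MT1X at 0.74 ± 0.09. The values with an estimated correlation, where none of these passed, were again the highest over the alternatives, and the lowest were 2.0e-14, 5.5e-05 and 8.8e-06.

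Genes at least 16-fold higher in SKOV3ip1 alone, and undetected in adipocytes alone, gave an apparent share of SKOV3ip1 RNA of 1.40% ± 0.065 (SD, n = 3) on co-cultured adipocyte arrays, over 151 genes. The share was 2.17% without background correction, 1.77% with genes at least 64-fold higher and 2.86% with the fixed marker list. Of these, 136 (90.1%) rose on all 3 arrays, and the 90th percentile of the share over genes was 4.13%. The next 3 gene groups had 0 rises against mixing. At baseline 17 of 17, 27 of 28 and 16 of 17 of their tested genes were higher in SKOV3ip1. A rise within adipocytes would seldom pass that level, so the count cannot part it from SKOV3ip1 RNA. Epithelial cancer cell genes rose for 8 and fell for 0 of 9 (median 2.88, adjusted p = 1.3e-15, 0.0504 with an estimated correlation), with ERBB2, a receptor tyrosine kinase, at 2.88 ± 0.10. Cell cycle genes rose for 14 and fell for 0 of 22 (adjusted over the list alone, 16 rose, median 0.84, or 0.69 with 8 genes at their bound, adjusted p = 2.4e-15, then 0.0504), with CDC20 at 2.96 ± 0.11, CCNB2 at least 3.35-fold and TOP2A at least 3.23-fold. Glycolysis genes rose for 4 and fell for 0 of 16 (median 0.16, adjusted p = 0.0025, then 0.208, range 0.00045 to 0.464 over the alternatives), with PFKP at 2.18 ± 0.12 and PKM at 0.59 ± 0.10. With the share set at its 90th percentile and subtracted, the glycolysis list no longer passed (adjusted p = 0.464), PFKP and PKM were at -0.60 and -0.16, and KRT19 (0.68) and MAL (1.20) lost their calls. The lowest adjusted p over the alternatives was 4.9e-17 for epithelial cancer cell and 2.5e-16 for cell cycle genes, and 0 of the 3 lists passed with an estimated correlation.

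On co-cultured SKOV3ip1 arrays the same measure of adipocyte RNA was 0.0401% ± 0.0049 (SD, n = 3) over 182 genes, of which 34.6% rose on all 3 arrays, and 0.0143% with genes at least 64-fold higher or 0.0149% with the fixed marker list. Abundant adipocyte transcripts gave low shares, at -0.0042% for ADIPOQ, adiponectin, 0.0103% for PLIN1, perilipin, and 0.0325% for GPX3. Higher shares were led by PTBP2 (8.21%), LGALS8 (5.03%) and RGS2 (4.81%). Genes named elsewhere in the text with higher shares included DCN (1.69%), PDK4 (1.63%), G0S2 (2.51%), OAS2 (2.68%) and IFI44 (2.41%). Subtracting so small a share changed few calls: 5387 genes passed, 5386 of them shared with the 5393.

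**Figure D3:**
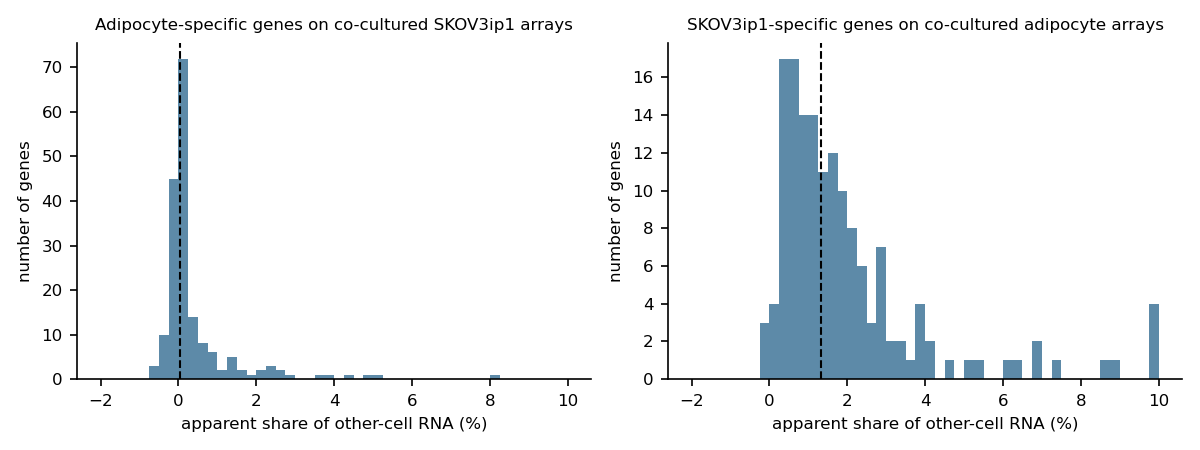
Apparent share of other-cell RNA (%) for each gene specific to the other cell type, on co-cultured SKOV3ip1 and adipocyte arrays; the dashed line is the median over genes, and values past the axis sit in its end bins. The adipocyte arrays center on 1.33% and the SKOV3ip1 arrays on 0.04%.

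The other lists did not pass in adipocytes. NF-kB and inflammatory cytokine genes rose for 3 and fell for 8 of 24 (adjusted over the list alone, 9 fell, median -0.23, adjusted p = 0.0573), with CXCL2, a chemokine, at -1.15 ± 0.11 and TNFAIP3 at -0.69 ± 0.09. Cytosolic heat shock genes rose for 0 and fell for 4 of 12 (adjusted p = 0.0987), with DNAJB1 at -0.48. Unfolded protein response genes rose for 2 and fell for 1 of 15 (adjusted over the list alone, 4 and 2, adjusted p = 0.188), with MANF at 0.56. Fatty acid uptake and lipid droplet genes rose for 4 and fell for 3 of 14 (adjusted p = 0.210), with G0S2 at 1.48 ± 0.10, HILPDA, a lipid droplet protein, at 1.11 ± 0.08 and PLIN3 at 0.80 ± 0.09. PPAR target genes rose for 4 and fell for 2 of 13 (adjusted p = 0.209), with ACSL1 at 0.59 and ANGPTL4 at 0.53. Fatty acid oxidation genes rose for 1 and fell for 2 of 17 (adjusted over the list alone, 0 and 2, adjusted p = 0.674). Glycerol-3-phosphate and triglyceride synthesis genes rose for 1 and fell for 2 of 11 (adjusted p = 0.439), and lipolysis genes rose for 1 and fell for 1 of 10 (adjusted over the list alone, 1 and 2, adjusted p = 0.991). Hypoxia (HIF) target genes rose for 4 and fell for 3 of 22 (adjusted over the list alone, 4 and 4, adjusted p = 0.539). Oxidative phosphorylation genes rose for 1 and fell for 0 of 28 (adjusted over the list alone, 0 and 0, adjusted p = 0.472). Ribosomal protein genes rose for 1 and fell for 0 of 26 (adjusted p = 0.168). Extracellular matrix and protease genes rose for 1 and fell for 5 of 17 (adjusted p = 0.613), with PLAU, urokinase, at least 1.75-fold higher but at -0.40 after subtraction of the 90th percentile share. Epithelial to mesenchymal transition genes rose for 2 and fell for 3 of 11 (adjusted p = 0.469), with CCN2 at -0.62.

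Adipocyte identity genes rose for 1 and fell for 1 of 22 (adjusted over the list alone, 0 and 0, median -0.01, or 0.01 with median scaling, adjusted p = 0.991), with PCK1 at 0.42 and LEP, leptin, at -0.34. Fibroblast and preadipocyte genes rose for 0 and fell for 3 of 10 (adjusted over the list alone, 4 fell, median -0.28, adjusted p = 0.168), with DCN at -0.44 and COL3A1 at -0.42. The endothelial genes CLDN5 (-0.91 ± 0.18, detected on 1 of 3 co-cultured arrays) and RAMP2 (-0.76 ± 0.13) fell. The macrophage genes CD68 (0.19), CD14 (-0.04) and AIF1 (-0.27) did not pass, nor did the red blood cell genes HBA2 (-0.26) and HBB (-0.14), and 0 T cell genes were detected. Of the mesothelial genes, KLK11 and MSLN were at least 1.77-fold and 1.64-fold higher, MSLN was at -0.32 after that subtraction, and CALB2 was at -0.03. The median and mean differed in sign for adipocyte identity and lipolysis genes. Of the 25 lists tested, 10 passed with camera and 15 with fry. None passed with an estimated correlation in camera, although 6 had an unadjusted p under 0.05.

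**Figure D4:**
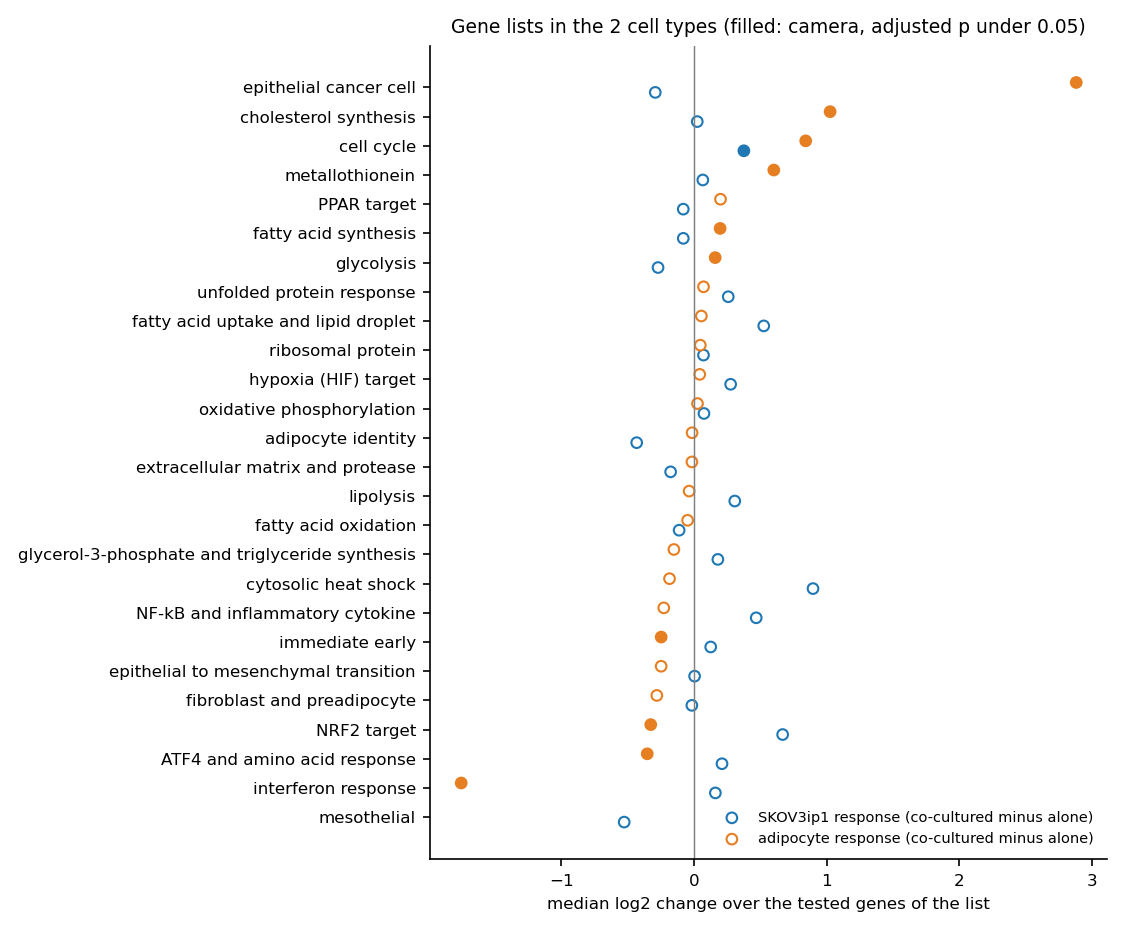
Median log2 change of each gene list in SKOV3ip1 cells and in adipocytes; filled points passed camera at an adjusted p under 0.05. In adipocytes 10 lists passed, and the interferon response list lay lowest at -1.75.

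The comparison of the responses asked whether both cell types changed the same genes. Across 8452 genes tested in both, Pearson's r was 0.001 and Spearman's rho was -0.005; genes are not independent replicates, so no p-value was computed. Both cell types raised 289 genes, against 275 for independent lists, and lowered 159, against 194. In SKOV3ip1 up and adipocytes down were 235, against 217, and the reverse held for 230, against 245.

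The test of the difference between the responses called 5396 of 11270 genes, 2699 with the higher change in adipocytes and 2697 in SKOV3ip1. Without co-cultured SKOV3ip1 replicate 2 it called 3548, and without co-cultured SKOV3ip1 replicate 3 it called 3594. With median scaling the split was 3457 and 1888. By fitted values ORM1, ORM2, MAL, KRT19 and CD24 were at 1 end, and CXCL8, OAS2, EPSTI1, IFI44L and IFI44 at the other, though OAS2 and IFI44 were undetected in SKOV3ip1 alone, MAL and CD24 in adipocytes alone, and ORM1, ORM2 and IFI44L in both SKOV3ip1 groups. Cholesterol synthesis genes moved apart by a median of 0.72 (camera adjusted p = 0.00014, 0.0374 with an estimated correlation). Epithelial cancer cell genes moved apart by 1.29 (camera adjusted p = 7.2e-11, 0.0147 with an estimated correlation). In adipocytes 0 of the 8 epithelial cancer cell rises went against mixing, so SKOV3ip1 RNA may give part of that gap. Interferon response genes moved apart by -2.08, with 19 of 21 higher in SKOV3ip1 (2.6e-13, 0.141 with an estimated correlation).

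**Figure D5:**
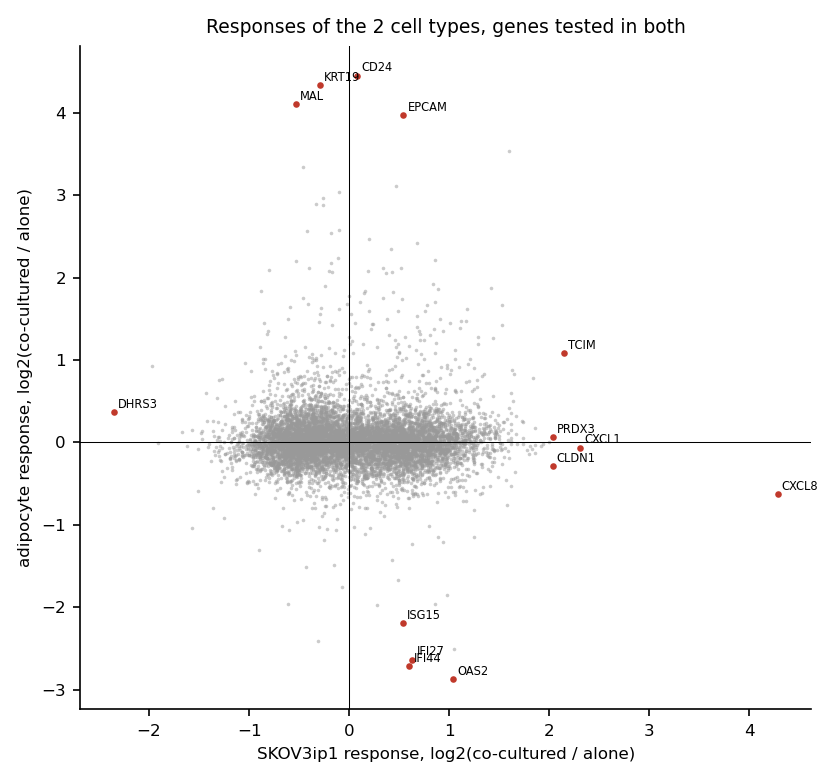
Log2 change in SKOV3ip1 cells (x axis) and in adipocytes (y axis) for the 8452 genes tested in both, 1 point per gene, with leading genes labelled. The changes were uncorrelated across genes, with r at 0.001.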

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

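Of the tests in this part, those of other-cell RNA (adipocyte RNA in SKOV3ip1, SKOV3ip1 RNA in adipocytes, its ratio between genes, and dilution) were chosen only after the result was seen, as were the covariate fit, the removal of replicate 1, the grouping of the splits, the splits that part the SKOV3ip1 pairs, the bounds on genes that moved apart and an added condition in the test for lost cell types. Adipocyte RNA in SKOV3ip1 was tested 4 times in turn: by subtraction of its share, which moved too little to decide, by calls that moved away from the adipocyte level, by changes against mixing, added when their count was known, and last by the calls within reach of its share. No group held enough samples to test for a sample far from the others.

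The responses of the cell types differed by the interaction test for 5396 genes. Of 100 drawn splits of the arrays within each cell type, 1, the real one, gave as many, and the highest other gave 4869, so chance was excluded by this count, though only against no response in either cell type. The splits do not test whether the responses were equal. The 8 drawn splits that kept the real grouping of SKOV3ip1 gave 3055 to 4869 genes, the 11 that kept that of adipocytes gave 120 to 431, and the 80 that kept neither gave 0. The drawn splits ignore the pairs of same-numbered samples in SKOV3ip1, of which only replicate 1 stood apart from the others. Of the 80 splits that part all 3 pairs there, 1, the real one, gave as many. The split that mirrored the adipocyte groups gave 4869, the 18 others that kept the real grouping of SKOV3ip1 gave 3055 to 3829, the 6 that kept that of adipocytes gave 119 to 172, and the 54 others gave 0. The count of 5396 thus rests largely on the SKOV3ip1 response. In each comparison of 3 against 3 arrays, 1 of 10 splits, the real one, gave as many genes, which is too few splits for a share below 0.1. The real counts were 5393 in SKOV3ip1, 2097 in adipocytes and 9703 at baseline, and the highest other was 0 in each. In SKOV3ip1, 4 of the 10 splits part as many same-numbered pairs as the real one, and the other 3 gave 0.

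Lists that moved apart, as the median of adipocyte minus SKOV3ip1 change, were epithelial cancer cell (1.29), mesothelial (0.934), cholesterol synthesis (0.716), fatty acid synthesis (0.383) and glycolysis (0.381) genes. Higher in SKOV3ip1 were interferon response (-2.08), NRF2 target (-0.981), cytosolic heat shock (-0.623), NF-kB and inflammatory cytokine (-0.316) and ATF4 and amino acid response (-0.250) genes. With an estimated correlation, epithelial cancer cell (adjusted p = 0.0147) and cholesterol synthesis genes (0.0374) still passed. In adipocytes the epithelial cancer cell and glycolysis lists had 0 rises against mixing. With the 90th percentile SKOV3ip1 share subtracted, the adipocyte glycolysis list no longer passed (camera adjusted p = 0.464), and MSLN, a mesothelial gene, was at -0.32. SKOV3ip1 RNA may thus give part of the epithelial cancer cell, mesothelial and glycolysis gaps. Genes at the ends of the fitted differences were ORM1 (5.09), ORM2 (4.68), MAL (4.64), KRT19 (4.62) and CD24 (4.37) on the adipocyte side. On the SKOV3ip1 side they were CXCL8 (-4.90), OAS2 (-3.90), EPSTI1 (-3.55), IFI44L (-3.36) and IFI44 (-3.32). These fitted values include groups that were undetected. With such groups at the lowest detected signal, MAL was at 4.25, CD24 at 3.95, OAS2 at -3.30 and IFI44 at -2.93. ORM1, ORM2 and IFI44L were undetected on every SKOV3ip1 array, so their differences are those of the adipocytes. Probes without a single gene name, which no comparison used, also changed: 1198 of 2777 tested in SKOV3ip1 (43.1%) and 213 of 2851 in adipocytes (7.47%). These shares lay below those of named genes, at 55.4% and 21.0%.

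The breadth of the SKOV3ip1 response was weighed against array quality and other-cell RNA. Adipocyte RNA was excluded as the whole cause. Even at the 90th percentile of its apparent share over genes (1.47%), it could give 65 of the 5393 calls (1.21%) within 2 standard errors, all of them rises, and for these 65 it stayed open. ADIPOQ and PLIN1 gave shares of -0.0042% and 0.0103%. Of the 1547 changes against mixing (28.7%), which adipocyte RNA cannot produce, 1127 lay past the mean of both adipocyte groups by over 2 standard errors of the response. The false calls allowed among all 5393 calls were 270, and the number expected past those means was not computed. A narrower count, of calls that moved away from the level of both adipocyte groups, was 769 (14.3%), fewer than the share written down before that count for excluding it, so that count alone did not decide. A gradient of array quality stayed open: differences between arrays of 1 group, ordered by detected probes, correlated across genes at 0.427 on average with the response on other arrays. Of 6 such correlations 4 were above 0, all with replicate 1 as the array with fewer detected probes, at gaps of at least 850. The 2 without replicate 1 in the difference, with gaps of 401 and 57, were at -0.13 and -0.11. The 4 thus share how replicate 1 stood apart and are not separate evidence of a gradient. Quality and a graded response to co-culture cannot be told apart, because detected probes differed with condition, and part of the 5393 calls may follow either.

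The rise of SKOV3ip1-specific genes in adipocytes was weighed as SKOV3ip1 RNA against a change in the adipocytes. Of the 151 genes 90.1% rose on all 3 co-cultured arrays whatever their function, a pattern consistent with SKOV3ip1 RNA, or a few SKOV3ip1 cells, in the adipocyte samples. Whether 1 source explains every gene stayed open, since 74.8% lay within 3-fold of the median share. EPCAM (15.7%), MECOM (14.9%), TM4SF4 (12.9%) and SPP1 (30.2%) lay above it, and were singled out after their values were seen. A rise of such genes within adipocytes was not tested.

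The fall of interferon genes in adipocytes was weighed against dilution, lost cell types and different preparations. Dilution was excluded, since the median fell by 1.753 and the 90th percentile share would give -0.0608. Loss of macrophages, T cells or endothelial cells stayed open. The 5 of 28 members detected had a median of -0.274, past the bound set beforehand by less than its spread, 0 of them were T cell genes, the 3 macrophage genes had a median of -0.04, and the endothelial genes CLDN5 (-0.91) and RAMP2 (-0.76) fell. Different adipocyte preparations in the groups stayed open: the closest arrays of the groups lay -1.60 apart, and the labels name no donor or day. An effect of co-culture, which the design names, stays open beside these and may explain the fall.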

How the results depend on the processing

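Of the alternatives in this part, the covariate, the removal of both replicate 1 arrays, the subtraction of other-cell RNA and the list tests under median scaling or within-cell-type neqc were chosen only after the result was seen. Over all alternatives the named genes kept their side of the threshold in 4422 results, with 209 weaker, 30 stronger and 7 reversed. Direction was compared only where a gene or list passed in either fit, so those that passed in neither may have changed sign. Lists kept their side in 719, with 15 weaker and 31 stronger, and their direction was that of the list test, not of the median. The authors' values count among these alternatives without being an independent check, being close to neqc by construction. With detected probes as a covariate, 46 named SKOV3ip1 genes lost their call, and 73 kept their side of the threshold. Where no cause is stated below, the cause was not tested.

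Called genes in SKOV3ip1 (5393) were 808 with a log2 change of at least 1, a stricter demand, and 837 with the covariate. Leaving out 1 array gave 3115 (without co-cultured replicate 3) to 7301 (without co-cultured replicate 1), with 3420 without SKOV3ip1 alone replicate 1 and 3160 without co-cultured replicate 2. In adipocytes (2097) they were 207 with a change of at least 1 and 1136 with a spread shared over the 4 groups, with 1442 to 1865 for single arrays left out. For the difference (5396) single arrays gave 3548 (without co-cultured SKOV3ip1 replicate 2), 3594 (without replicate 3) and up to 6907, and at baseline 9497 to 9853. A replicate block gave 6788 genes in SKOV3ip1, 2003 in adipocytes, 9698 at baseline and 6503 for the difference. It left 1 and 10 lists and changed named calls for CCN1 and MT1E in SKOV3ip1 and CPT2, RPS3 and XBP1 in adipocytes.

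Lists that passed in SKOV3ip1 (1) were 2 without background correction, 0 with an estimated correlation, 0 with median scaling, 0 without both replicate 1 arrays, 11 with fry and 0 to 3 with single arrays left out. The 0 came without co-cultured replicate 1; without SKOV3ip1 alone replicate 1 or co-cultured replicate 3 there were 3, and without co-cultured replicate 2 there were 2. Fry asks whether genes move 1 way and compares a list with no other genes. In adipocytes (10) they were 0 with an estimated correlation and 10 to 12 with single arrays left out. NF-kB and inflammatory cytokine genes also passed without adipocytes alone replicate 3 or co-cultured replicate 3, and fibroblast and preadipocyte genes without the latter.

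The apparent share on SKOV3ip1 arrays (0.0401%) was 0.0461% without background correction, 0.0143% with genes at least 64-fold higher, 0.0149% with the fixed marker list and 0.0369% to 0.0471% with single arrays left out. On adipocyte arrays (1.40%) it was 2.17%, 1.77% and 2.86% under the same choices, 1.67% with the authors' values and 1.36% to 1.48% with single arrays left out. The correlation of the responses was -0.583 among genes against mixing in both, which that choice fixes by construction, and -0.0219 to 0.0193 with single arrays left out.

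In adipocytes TGFBI reversed to -0.14 with the share subtracted. With the 90th percentile share subtracted, TGFBI was at -0.48, MSLN at -0.32, PFKP at -0.60, PKM at -0.16, BIRC5 at -0.32 and PLAU at -0.40, as a larger subtraction must lower them. Signal over background limits genes undetected in 1 group, whose folds are lower bounds.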

Other observations

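The tests of this part, on 4 lists, were all chosen only after the leading genes had been seen, though before the members of those lists were read. Of 8 acute phase genes in adipocytes 4 rose (median 0.403, camera adjusted p = 0.0095 over 8 tests, 0.311 with an estimated correlation). CFB, complement factor B, rose by 1.08 ± 0.13 and C3, complement C3, by 0.74 ± 0.17, whereas SAA1 did not pass (0.17). LCN2, another of the 4, rose by 0.48 ± 0.10 but was specific to SKOV3ip1 and undetected in adipocytes alone. Its apparent share of 1.08% lay below the median of 1.33%, so SKOV3ip1 RNA may account for its rise. The list median lies between LCN2 and BCL3, which did not pass (0.33). The other rises leave a wider acute phase programme beside ORM1, HP and SAA2 as a hypothesis only. TGF-beta target genes in adipocytes rose for 7 and fell for 1 of 13 (median 0.54, adjusted p = 0.0014, 0.311 with an estimated correlation), with ID1 at 2.07, ID3 at 1.24 and CCN2 at -0.62. That median was the value of TGFBI itself, a gene undetected in adipocytes alone. TGFBI was at -0.14 with the apparent SKOV3ip1 share subtracted and at -0.48 with the 90th percentile share. SMAD7 (0.25), SKIL (0.08), SKI (0.04), COL4A1 (0.11) and TPM1 (-0.04) did not pass. Which signal raised ID1 and ID3 was not tested, so the list name is no finding about TGF-beta.

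Other hypotheses stayed open. Glucocorticoid target genes in adipocytes had a median of 0.121 (adjusted p = 0.496), and in SKOV3ip1 they rose for 4 and fell for 0 of 7 without passing (median 0.618, adjusted p = 0.140). In SKOV3ip1, TGF-beta target genes rose for 1 and fell for 5 of 12 (median -0.304, adjusted p = 0.266), with SMAD7 at -1.04. Retinoic acid target genes there rose for 2 and fell for 2 of 7 (median -0.214, adjusted p = 0.883). Acute phase genes in SKOV3ip1 (median -0.0759, adjusted p = 0.883) and retinoic acid target genes in adipocytes (median 0.148, adjusted p = 0.496) did not pass. Neither the TGF-beta nor the retinoic acid list passed in SKOV3ip1 beside the falls of PMEPA1 and DHRS3.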
